A study of Mus musculus with 50 samples.

How the data were processed

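The series holds 50 single-oocyte RNA-seq samples, 26 from floxed and 24 from Zfp36l2 conditional knockout mice. Per the labels' protocols, the females were 5 weeks old and primed with 10 IU of PMSG, a gonadotrophin that drives follicle growth, and oocytes enclosed in cumulus cells were collected after 46 hours in medium with milrinone, which holds them in meiotic arrest. The surrounding cells and the zona pellucida were then removed. Per the labels' protocols, RNA was extracted with Trizol and cDNA was made with the SMARTer Ultra Low Input kit, which primes on poly(A) tails, amplifies whole cDNA by PCR, carries no molecular identifiers and does not mark strand.

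The authors deposited whole-number read counts per gene in 1 table of 16614 rows for all oocytes. Alignment with STAR to the mm10 build is named in the submitters' processing notes. The STAR version, the counting tool and its treatment of multi-mapping and duplicate reads are not given in the sources used here. The deposited counts were not normalized: totals per oocyte differed from 1746007 to 6233840. No mitochondrially encoded gene is listed in the table, and Zfp36l3 is not analysed here. Symbols had been turned into dates in 24 rows, and 29 rows join several symbols; these rows were kept under the names in the table. The highest count was 8354, and even counts made up 61.5% of counts from 1 to 20. Within floxed oocytes, the slope of log2 count on log2 library total had a median of 1.40 for genes with under 0.05 mean counts per base of transcript and 0.47 for genes with 0.8 or more. Whether this also compresses fold changes of abundant genes was not tested.

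Columns were matched to samples by the header name in the labels, or by the title where that name had another form (knockout oocyte 8 of 3 mice). No other column of sample values was present. Groups and mouse numbers come from the sample titles. The mouse was the replicate: counts of all oocytes of a mouse were summed, giving 4 floxed and 4 knockout sums. Before summing, all 150 pairs of oocytes of the same mouse were compared by a chi-square test of their counts. The statistic per degree of freedom was 5.41 to 29.82, so no pair was taken for copies of 1 library; the test says nothing else about how alike oocytes were, since PCR copies are not independent.

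Sums were compared with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood test with robust estimation, Benjamini-Hochberg adjusted p under 0.05). The filter kept 15029 genes. CPM values are shares of a mouse's total count on the usual CPM scale, computed here from the deposited counts, and means ± SD are over mice. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation between mice was 35.4%. Intervals and shares cover counting and mouse-to-mouse error only, since PCR copies are not independent molecules.

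Before the data were examined, 26 gene lists, the tests and the alternatives were fixed. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 25 lists with tested members, with an estimated correlation and fry beside it. The list of mitochondrially encoded proteins had no member in the table. Genes named were those of a rule fixed at the same time: the ZFP36 family; the 8 highest and 8 lowest log2 fold changes among called genes with a mean CPM of 10 or more and no overlap of the groups, leaving out unnamed gene models; up to 4 called genes with the smallest p in each list; and the 6 smallest p overall. The rule gave 111 genes, of which 2 are not reported here. Keratin and myosin heavy chain genes named among the other observations were chosen after their values were seen.

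Shares of counts, genes detected and the spread between oocytes were averaged per mouse and compared by exact two-sided permutation of mice (70 arrangements for 4 against 4). Detection and spread used counts thinned to 3000000 per oocyte, and 3 shallower oocytes were left out. The spread was the SD of log2(CPM + 1) among oocytes of a mouse, over genes with a mean CPM of 10 or more, in the 7 mice with enough oocytes.

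Coordinates and 3′ untranslated regions come from GENCODE annotation of mm10. Rows were matched to it by RefSeq accession (16350) or by symbol (186), and 78 rows were not matched. The motif was counted in 13950 tested genes with an annotated 3′ untranslated region of at least 20 bases, and modelled by logistic regression in statsmodels 0.14.6 under Python 3.11.15. A simulated odds ratio of 1.5 was recovered as 1.63 (95% interval 1.49 to 1.78).

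The count tests were tested on simulated data for the comparison of 4 knockout and 4 floxed mice, with 200 changed genes among 14787. A list of further genes was planted at a 1.5-fold rise and is not counted in the recovery rates. The edgeR test recovered 3.0% of genes changed 1.5-fold, 28.4% of those changed 2-fold and 86.4% of those changed 4-fold, and 4.88% of its calls were unchanged genes. Unchanged genes made up 21.23% of the calls of DESeq2 1.42.0 and 7.23% of those of limma on mouse means. They made up 58.58% of those of voom on single oocytes with the mouse as a random effect. These 3 had been fixed as alternatives beforehand. Far fewer genes were changed in the simulation than the 27.6% called in the data, so its rates do not carry over to the data.

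Alternatives were another normalization, DESeq2, no or a stricter low-count filter, leaving out each mouse, the mouse number as a block, leaving out the knockout oocytes numbered 8, thinned oocytes, limma on mouse means, voom on oocytes, leaving out shallow oocytes or the 10 most abundant genes, a 1.5-fold minimum, an estimated correlation for lists, other depths, summaries and expression limits, and 2 other motifs.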

Results

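Single fully grown oocytes from mice with a conditional knockout of Zfp36l2 were compared with oocytes from floxed mice, which carry the targetable allele and served as controls. ZFP36L2 is an RNA-binding protein that binds AU-rich elements in 3′ untranslated regions and promotes decay of the bound mRNA. The oocytes were at the germinal vesicle stage, arrested in meiotic prophase, and each was sequenced as its own library. The 50 oocytes comprised 26 floxed and 24 knockout cells. The floxed oocytes came from 4 mice with 5, 7, 7 and 7 oocytes, and the knockout oocytes from 4 mice with 1, 7, 8 and 8. The mouse was the replicate, so the counts of its oocytes were summed. Total counts ranged from 1746007 to 6233840 per oocyte (median 5004426.5) and from 4332108 to 44498770 per mouse. Knockout mouse 1, with a single oocyte, had the lowest sum.

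Zfp36l2 itself (chromosome 17, 84183931 to 84187947, mm10) was low in both genotypes and was not significantly lower in the oocytes labelled knockout. Its level was 3.27 ± 0.934 CPM in floxed and 2.00 ± 0.806 CPM in knockout mice (SD, n = 4 each). The log2 fold change was −0.78 (SE 0.43, edgeR adjusted p = 0.208), with a 95% interval from −1.76 to 0.19. Per mouse the values were 3.51, 1.96, 4.17 and 3.44 CPM in floxed mice 1 to 4, against 2.77, 1.61, 2.56 and 1.06 CPM in knockout mice 1 to 4. Single floxed oocytes held 0 to 47 counts and single knockout oocytes 0 to 38. The count is per gene, so exons inside and outside the deleted part were not separated, and this row does not check the genotype labels. Knockout therefore denotes the oocytes so labelled throughout, and every direction given rests on those labels.

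The paralogue Zfp36, which encodes the founding member of the family (tristetraprolin), was 3.77-fold higher in knockout oocytes. It rose from 3.85 ± 1.37 to 14.7 ± 5.56 CPM (n = 4 mice each; log2 fold change 1.91, SE 0.36, adjusted p = 0.00504), and the lowest knockout mouse, at 8.08 CPM, exceeded the highest floxed mouse, at 5.76 CPM. Zfp36l1 was near the detection limit, at 1.14 ± 0.188 CPM in floxed and 0.845 ± 0.357 CPM in knockout mice (adjusted p = 0.566). As a list, the 3 family members tested had 1 higher and none lower, also adjusted over the list alone (camera adjusted p = 0.988).

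**Figure D1:**
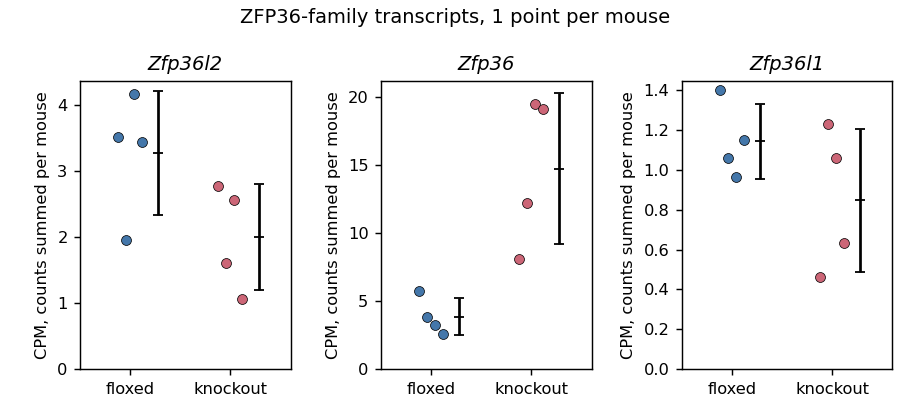
CPM of Zfp36l2, Zfp36 and Zfp36l1, with 1 point per mouse (mice 1 to 4 from left to right within a group) and the mean ± SD of 4 mice as a bar beside the points; the vertical scales differ. The knockout mice lie between 1.06 and 2.77 CPM for Zfp36l2, overlapping the floxed mice, and above every floxed mouse for Zfp36.

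Relative to the other genes, many transcripts differed between the genotypes, in both directions. CPM and TMM normalization centre the fold changes, with a median log2 fold change of −0.006 over all tested genes. A change in the total mRNA of an oocyte therefore cannot be seen, and rises and falls are relative throughout. Of 15029 genes tested, 2164 were higher and 1984 lower in knockout oocytes, together 27.6% of the tested genes (edgeR quasi-likelihood test on mouse sums, adjusted p under 0.05). At least 2-fold changes were seen for 1306 of the higher and 1036 of the lower genes, and at least 4-fold changes for 502 and 530. The 4 knockout mice lay entirely above or entirely below the 4 floxed mice for 31% of the tested genes, where chance gives 2.86%. The first principal component of single oocytes, with 39.3% of the variance, separated all 26 floxed from all 24 knockout oocytes. On the second component, with 9.8%, the mean of mouse 1 lay apart from those of the other mice in both genotypes, though 1 oocyte of floxed mouse 2 lay among those of floxed mouse 1. Without mouse 1 of either genotype, 3182 genes were higher and 3549 lower. Of these 6731 genes, 84.0% differed in the same direction between floxed mouse 1 and knockout mouse 1, a single pair that gives no test. Without floxed mouse 4 only 1219 genes were lower, and without knockout mouse 2 or 3 only 1359 or 1374 were higher.

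**Figure D2:**
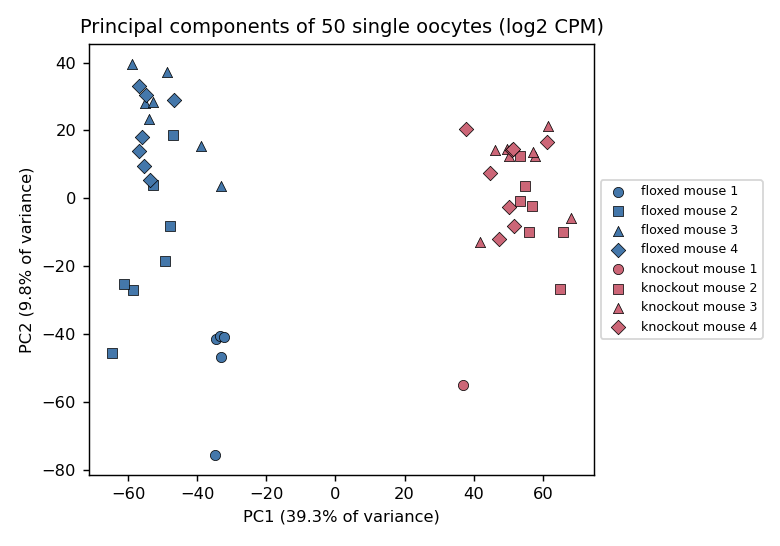
First against second principal component of log2 CPM, 1 point per oocyte, coloured by genotype with 1 marker shape per mouse number. The first component separates the genotypes, with mouse means from −54.5 to −33.6 in floxed and from 36.9 to 57.9 in knockout oocytes; mouse 1 of both genotypes has the lowest mean on the second (−49.1 and −54.9).

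Among called genes with a mean of 10 CPM or more and no overlap of the groups, the 8 that rose most had at most 6.74 CPM (Tpm4) in floxed oocytes. Agtr1a, the angiotensin II type 1a receptor (chromosome 13, 30336441 to 30382867), went from 0.182 ± 0.0845 to 51.1 ± 28.3 CPM (log2 fold change 8.07, SE 0.67, adjusted p = 0.000191). Stambpl1, a deubiquitinase (chromosome 19, 34192229 to 34240333), went from 1.09 ± 0.606 to 73.6 ± 18.3 CPM, a 65.3-fold rise (adjusted p = 0.00017). Adh7, an alcohol dehydrogenase that oxidises retinol, Gldn, known for its role at nodes of Ranvier, Scrn1, Zbtb5, a zinc finger protein, and the tropomyosin Tpm4 rose between 17.7-fold (Tpm4) and 83.9-fold (Adh7). Cuedc1 had the smallest p of all genes: 5.18 ± 0.62 CPM in floxed and 86.0 ± 3.29 CPM in knockout mice (adjusted p = 4.38e-06). Among the other genes with the smallest p, Hpse, the heparan sulfate-degrading enzyme heparanase, rose from 79.1 ± 12.9 to 380.5 ± 20.4 CPM, Aox4, an aldehyde oxidase, from 9.12 ± 1.81 to 148.9 ± 39.7 CPM, and Gcm2, a transcription factor of parathyroid development, from 38.3 ± 8.91 to 214.3 ± 14.3 CPM.

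Under the same limits, the 8 genes that fell most had at most 1.54 CPM (Crip2) in knockout oocytes. Oit1 (chromosome 14, 8348937 to 8378754) fell from 24.0 ± 8.85 to 0.113 ± 0.122 CPM, a log2 fold change of −7.39 (SE 0.62, adjusted p = 0.000191). Nyap2, a neuronal adaptor of phosphoinositide 3-kinase (chromosome 1, 81076950 to 81341764), fell from 36.3 ± 9.98 to 0.237 ± 0.213 CPM (log2 fold change −6.97, SE 0.50, adjusted p = 0.000169). Apba2, Prr32, the Krüppel-like transcription factor Glis1, Cpxm2, Crip2 and Bpifc were between 33.1-fold (Bpifc) and 92.7-fold (Apba2) lower. Ece1, the enzyme that activates endothelin, fell from 43.0 ± 6.95 to 2.17 ± 0.54 CPM (adjusted p = 8.45e-05). One mouse stood apart within its group for Oit1 and Tpm4 (floxed mouse 1) and for Apba2 and Adh7 (knockout mouse 1), without overlap of the groups.

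**Figure D3:**
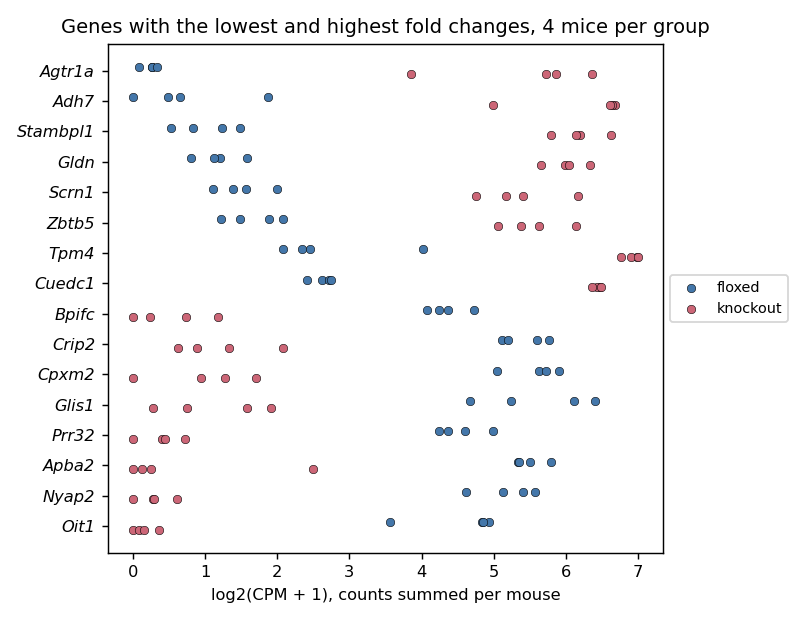
Levels of the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean of 10 CPM or more and no overlap of the groups, as log2(CPM + 1) per mouse with 1 point for each of 4 mice per group. Of the genes shown, Agtr1a is highest in fold, from 0.182 CPM in floxed to 51.1 CPM in knockout mice, and Oit1 lowest, from 24.0 to 0.113 CPM.

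Histone-modifying genes formed the 2 lists that were higher as a whole by the main list test, camera with a preset correlation (adjusted p = 0.045 each). With an estimated correlation neither was (adjusted p = 0.863 for both). Of 22 histone lysine demethylases, 9 rose, none fell and 13 did not pass (9 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.68. Kdm5a, which removes methyl groups from lysine 4 of histone H3, rose 3.84-fold, from 9.43 ± 1.84 to 37.2 ± 4.02 CPM (n = 4 mice each, adjusted p = 0.000368). Kdm1b, needed for DNA methylation imprints in oocytes, rose 1.7-fold, from 247.7 ± 28.7 to 431.5 ± 29.0 CPM (adjusted p = 0.00079). Kdm5c and Phf2 rose 1.89-fold and 2.68-fold. Of 31 genes of histone acetylation and deacetylation, 9 rose and none fell (also adjusted over the list alone). They include both writers and erasers: the deacetylases Hdac11 (13.8-fold) and Sirt1 (3.48-fold, from 53.1 ± 16.7 to 188.6 ± 26.7 CPM), and the coactivators Ncoa2 (1.48-fold) and Ncoa1 (1.57-fold), which have acetyltransferase activity. The fry test asks only whether a list's genes move one way and does not compare them with other genes. It gave an adjusted p of 0.00353 for both lists, and in all it placed 6 lists higher and 4 lower. Neither list passed camera when floxed mouse 1, or knockout mouse 1, 2 or 3, was left out, nor without mouse 1 of both genotypes, and the acetylation list did not without knockout mouse 4 (adjusted p = 0.118).

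Related lists had more higher than lower members but did not pass camera. Of 42 ATP-dependent chromatin remodellers, 12 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.267), among them Chd1 (1.98-fold, from 33.1 ± 6.05 to 67.4 ± 5.08 CPM), Chd9 (1.58-fold), the SWI/SNF subunit Arid2 (1.51-fold) and the NuRD subunit Mta2 (4.66-fold). Of 33 histone lysine methyltransferases, 6 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.515). Setd1b, an H3 lysine 4 methyltransferase, rose 2.70-fold, Kmt2e 2.24-fold, and Ehmt2, the H3 lysine 9 methyltransferase G9a, rose from 2.82 ± 1.5 to 17.5 ± 3.83 CPM (6.09-fold). Among 30 Polycomb group genes 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.375). The chromobox genes Cbx2, Cbx7 and Cbx8 rose 1.38-fold, 3.81-fold and 9.91-fold.

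Genes of DNA methylation and demethylation changed in both directions. Of 16 members, 3 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.559). Tet2, a dioxygenase that oxidises 5-methylcytosine, rose 3.56-fold, from 16.9 ± 2.84 to 62.0 ± 10.9 CPM. Tet1, which catalyses the same reaction, fell 6.13-fold, from 29.9 ± 7.93 to 4.90 ± 2.71 CPM (adjusted p = 0.00205). The de novo methyltransferase Dnmt3b rose 2.11-fold, from 45.9 ± 7.47 to 99.3 ± 9.84 CPM, and Uhrf2 5.38-fold.

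Zinc finger genes named Zfp plus a number had 66 higher and 40 lower members among 303 tested (69 and 49 adjusted over the list alone; camera adjusted p = 0.267). Zfp937 rose from 54.1 ± 13.5 to 229.6 ± 17.7 CPM, Zfp617 4.50-fold, Zfp704 3.13-fold and Zfp953 11.5-fold. Many genes of this family are similar in sequence, and how reads shared between them were counted is not given in the sources used here, so these values are uncertain.

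In the general transcription machinery 3 of 56 genes rose and 5 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.375). Taf9b, a TFIID and coactivator subunit, fell 3.92-fold, from 283.9 ± 42.8 to 75.1 ± 22.8 CPM (adjusted p = 0.000534). Tbpl1, a TBP-related factor, fell 3.2-fold, and Taf1, the largest TFIID subunit, 1.71-fold, whereas Nelfb rose 1.75-fold. Among 32 Mediator genes 5 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.988). Med13 and Med13l, of the kinase module, rose 2.29-fold and 1.68-fold, and Med31 and Med7 fell 1.35-fold and 1.42-fold. Nelfb did not pass without knockout mouse 3, Med31 without floxed mouse 4, and Med7 without floxed mouse 2 or knockout mouse 2, 3 or 4. The Mediator list's median was below 0 and its mean above 0 (−0.03 and 0.11 on the log2 scale).

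Genes of mRNA turnover and translational control changed in both directions. Of 58 genes of deadenylation, decapping and decay, 10 rose and 5 fell (the same adjusted over the list alone; camera adjusted p = 0.515). Ddx6, a helicase that represses translation and promotes decapping of mRNA, rose 1.98-fold from 51.3 ± 5.97 to 104.6 ± 9.43 CPM. The deadenylase Parn rose 1.85-fold and Smg5, of nonsense-mediated decay, 4.16-fold, whereas Upf3b of the same pathway fell 1.99-fold. Among 38 genes that control translation or the poly(A) tail of maternal mRNA, 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.988). The poly(A)-binding protein Pabpc1 rose 4.44-fold, from 17.7 ± 5.25 to 80.3 ± 7.08 CPM, and Msi2, an RNA-binding translational regulator, fell 8.06-fold, from 14.5 ± 3.24 to 1.72 ± 1.03 CPM (adjusted p = 0.00144). Of 26 tested mRNAs reported elsewhere as targets of the ZFP36 family, 6 rose and 3 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.948). Mcl1, an anti-apoptotic BCL2 relative, rose from 10.1 ± 4.84 to 49.2 ± 12.8 CPM (4.79-fold) and Nfkbiz 2.62-fold, while Hif1a fell 1.27-fold. Without floxed mouse 2 Nfkbiz did not pass the threshold.

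Small-RNA and transposon-silencing genes included some of the largest changes among the fixed lists. Of 28 members, 4 rose and 7 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.341). The PIWI gene Piwil2 rose 8.21-fold, from 4.72 ± 1.22 to 39.8 ± 6.09 CPM (adjusted p = 0.000191), while its relative Piwil1 fell 21.3-fold, from 35.01 ± 8.84 to 1.55 ± 1.52 CPM (adjusted p = 0.00362). Mov10, an RNA helicase, rose 3.73-fold and the germ cell helicase Ddx4 1.91-fold.

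Few genes of oocyte identity were called, where 27.6% of all tested genes were. The most abundant genes were called less often, in 17.8% of the 163 genes at 0.8 or more mean counts per base of transcript. From 0.2 to 0.4 and from 0.4 to 0.8 the shares were 24.1% and 24.6%. Whether abundance accounts for the few calls was not tested, so they do not show that genes of oocyte identity were spared. Of 39 oocyte-specific and maternal-effect genes, 2 rose and 4 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.267). Without floxed mouse 3 the list was lower by camera with the preset correlation (adjusted p = 0.0328). With the correlation estimated from all mice, 0.473 for this list, camera gave an adjusted p of 0.988. Figla, a transcription factor of follicle formation, rose 1.63-fold, from 50.3 ± 8.61 to 83.7 ± 8.14 CPM. Mos, the kinase of metaphase II arrest, fell 1.25-fold, from 314.6 ± 19.5 to 258.6 ± 17.0 CPM. Among 56 genes of meiotic arrest and the cell cycle 4 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.515). Prkar2b, a regulatory subunit of protein kinase A, fell 6.58-fold, from 70.6 ± 19.0 to 10.9 ± 3.21 CPM. Gpr12, a receptor that raises cyclic AMP, fell 13.1-fold and the meiotic cohesin Smc1b 2.40-fold, whereas the phosphatase Cdc25b, which activates CDK1, rose 1.62-fold from 78.5 ± 5.28 to 130.4 ± 9.35 CPM.

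Called genes of stress and cell death went in both directions. Of 31 immediate-early and heat-shock stress genes 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.267). Sqstm1 rose 2.80-fold and Hmox1, haem oxygenase, 5.22-fold, from 7.21 ± 1.85 to 38.7 ± 25.3 CPM. Among 27 genes of apoptosis and the DNA damage response 4 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.515). The pro-apoptotic Bcl2l11 fell 3.90-fold, from 30.5 ± 3.12 to 8.06 ± 1.29 CPM, and Trp73, a p53 relative, fell 8.16-fold. Of 18 genes of the 2-cell stage 5 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.988). Those with the smallest p, Obox3, Eif1a and Tdpoz1, rose but have near-identical copies and are uncertain. That list's median and mean were above 0 while camera pointed down, and signs also differed in the ZFP36 family, cumulus and proteasome lists. One mouse stood apart within its group for Hif1a, Gpr12, Mos, Sqstm1, Trp73 and Pecam1, without overlap of the groups.

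Housekeeping lists had few called members as well. Whether abundance accounts for this was not tested, so it does not show that they were spared. Among 83 cytosolic ribosomal protein genes 3 rose and 3 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.515), with Rpl19 at 75.02 ± 4.06 CPM in floxed and 43.9 ± 3.02 CPM in knockout mice and Rpl9 higher 2.32-fold. Among 47 proteasome genes 2 rose and 3 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.897), with Psmd13 higher 2.74-fold. Among 77 nuclear-encoded respiratory chain genes 3 rose and 5 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.375), with Ndufb7 lower 1.87-fold and Uqcrc1 higher 2.78-fold. No list was lower by camera at an adjusted p under 0.05 in the main test. One was at an unadjusted p, and fry placed 6 lists higher and 4 lower.

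**Figure D4:**
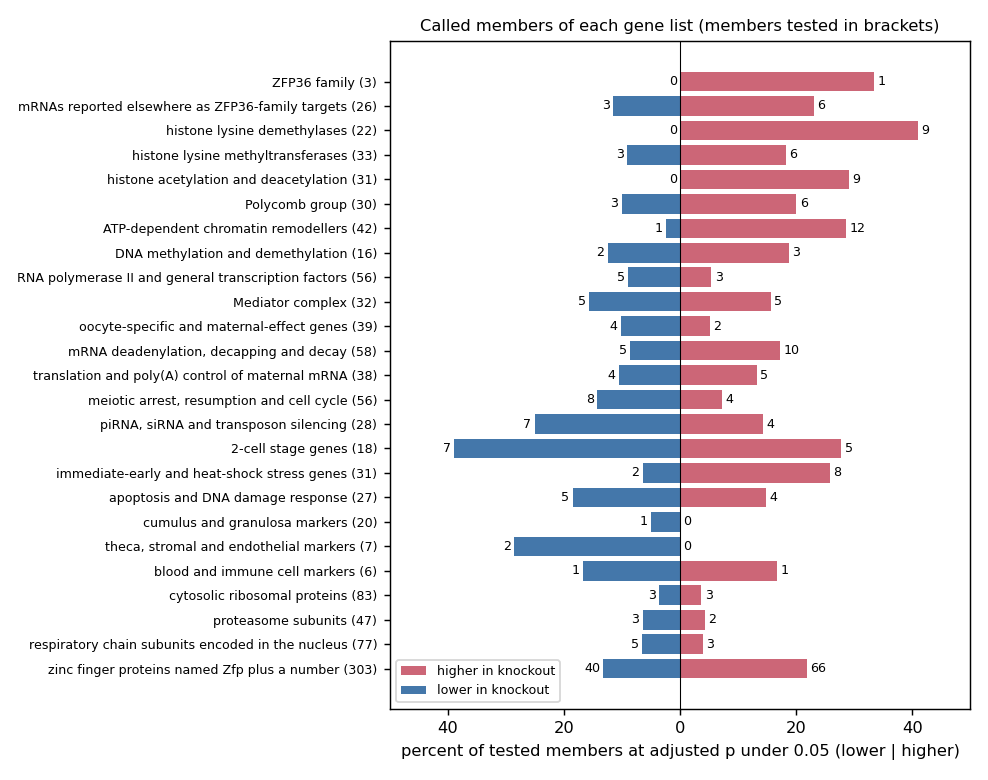
Percent of the tested members of each fixed list that were higher (right) or lower (left) in knockout oocytes, with the number of genes at each bar end and the number tested in brackets. Histone lysine demethylases have 9 higher and 0 lower of 22, and piRNA, siRNA and transposon silencing genes 4 higher and 7 lower of 28.

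Markers of other ovarian cells were compared because cumulus cells were stripped from the oocytes by hand. Of 20 cumulus and granulosa markers none rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.988). The 1 gene was Cyp11a1, at 3.88 ± 2.07 CPM in floxed mice, with no count in 3 of 4 knockout mice. These markers took 0.0957 ± 0.0056% of the counts of floxed and 0.0909 ± 0.0068% of those of knockout oocytes (exact permutation test on 4 against 4 mice, two-sided, p = 0.314, adjusted p = 0.393). Of 7 theca, stromal and endothelial markers 2 fell, also adjusted over the list alone (camera adjusted p = 0.559), and their share was 0.0157 ± 0.00394% against 0.00322 ± 0.000639% (exact p = 0.0286, adjusted p = 0.0714). No smaller exact p can come from 70 arrangements, and over 5 shares it passes only if at least 3 shares reach it. Nearly all of it was Pecam1, an adhesion molecule of endothelial cells, at 150.4 ± 39.9 CPM in floxed and 27.0 ± 8.08 CPM in knockout mice (adjusted p = 0.000487). Of 6 blood and immune markers 1 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.897), and their share was 0.00719 ± 0.0016% against 0.00377 ± 0.000422% (exact p = 0.0286, adjusted p = 0.0714). Most of it was the complement gene C1qb, at 63.0 ± 14.7 CPM in floxed and 30.3 ± 3.61 CPM in knockout mice. Ribosomal protein genes took 0.53 ± 0.0599% and 0.507 ± 0.0165% (exact p = 0.571), and the 10 most abundant genes 1.09 ± 0.108% and 0.971 ± 0.0259% (exact p = 0.0857; 5 shares tested).

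Genes detected per oocyte and the spread between oocytes were compared at equal depth. In the 47 oocytes that reached 3000000 counts, 13953.8 ± 201.8 genes were detected in floxed and 13811.0 ± 68.6 in knockout mice (SD of 4 mouse means, exact permutation p = 0.171). Without thinning the numbers were 13980.3 ± 244.7 and 13977.0 ± 100.7. Oocytes of the same mouse differed by a mean SD of 0.312 ± 0.055 on the log2 scale in 4 floxed and 0.387 ± 0.006 in 3 knockout mice, over 9711 genes (exact permutation p = 0.0571). This difference of 0.075 was 0.048 without floxed mouse 1, and 0.041 over the 5751 genes with a mean CPM of 50 or more (exact permutation p = 0.143).

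The AU-rich heptamer TATTTAT, which ZFP36-family proteins bind as RNA, was sought in annotated 3′ untranslated regions. It occurred in 32.7% of the 2052 higher genes with a searchable 3′ untranslated region and in 28.4% of the other tested genes (Fisher's exact test, odds ratio 1.23, p = 8.68e-05). The higher genes also had longer 3′ untranslated regions (median 1312.5 against 1052.5 bases). With length, A+T share and expression in a logistic model, the odds ratio was 1.08 (95% interval 0.968 to 1.21, p = 0.163). Among the 1841 lower genes the heptamer was less frequent, at 26.3% against 29.4% of the other genes, with an odds ratio of 0.816 in the same kind of model (0.721 to 0.923, p = 0.00125). The longer motif TTATTTATT, which contains the heptamer, was also less frequent among lower genes, at 6.2% against 8.1% (model odds ratio 0.758, 0.618 to 0.93, p = 0.00803). The shorter motif ATTTA did not differ among lower genes, at 69.3% against 69.0% (model odds ratio 0.978, 0.851 to 1.13, p = 0.758).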

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

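In 231 groups of 4 mice, for the named genes reported, count shares, genes detected and spread, 15 held 1 mouse far from its group (by Dixon's test for 4 values). Chance alone gives about 11.6. The tests of why mouse 1 stands apart were chosen after that result was seen.

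Mouse 1 of a genotype was the distant one in 9 of the 15. In floxed mouse 1, Oit1 was at 10.8 CPM (other floxed mice 27.7 to 29.7), Tpm4 at 15.2 (3.23 to 4.46), Usp17ld at 0.701 (0.0816 to 0.186) and Pecam1 at 91.1 (162 to 175). In knockout mouse 1, Apba2 was at 4.62 CPM (other knockout mice 0 to 0.188), Adh7 at 30.7 (97.3 to 102), Mos at 284 (248 to 251), Sqstm1 at 191 (98.3 to 110) and Trp73 at 7.62 (2.85 to 3.65). The others lay in mice 2 and 3. In floxed mouse 2, Hif1a was at 262 CPM (276 to 278) and Cd74 at 0.0816, with 0 in the other floxed mice. Gpr12 was at 6.26 CPM (3.60 to 3.91) and Rpl39l at 76.9 (80.4 to 81.0) in floxed mouse 3. In knockout mice, Cyp11a1 was at 0.135 CPM in mouse 3 with 0 in the others, and ribosomal protein genes took 0.532% of counts in mouse 3 (0.497 to 0.501).

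Mouse 1 of both genotypes also shared a position on the second principal component. Across 10957 genes, which are not independent replicates, its deviations in mean log2(CPM + 1) over oocytes from the mean of the other 3 mice of its genotype correlated between the genotypes (r = 0.58; other pairs of a floxed and a knockout mouse gave −0.51 to 0.47). These deviations rose with transcript GC content in both genotypes (Spearman rho 0.38 in floxed and 0.29 in knockout mouse 1). Trends of like size but opposite sign were seen in floxed mice 3 and 4 (rho −0.34 and −0.4). Deviations of mice within a genotype are linked by construction, and a GC trend is not particular to mouse 1. A GC-dependent difference in library preparation or sequencing is therefore only a candidate explanation. Lower depth as the whole explanation is argued against. Oocytes of other mice with totals within 10% of the mouse 1 range lay apart from mouse 1 on that component, with means 57.4 away in floxed (8 oocytes of 2 mice, SD 19.4) and 57.5 away in knockout mice (6 oocytes of 3 mice, SD 19.0; knockout mouse 1 is 1 oocyte). With every oocyte thinned to 1500000 counts, rho stayed at 0.37 and 0.28. Random thinning keeps each gene's expected share of counts, so rho could hardly move, and this decides nothing about depth. A part played by depth stays open, since floxed mouse 2, which has the shallowest oocytes, had a rho of 0.18, although knockout mouse 2, the shallowest knockout mouse after mouse 1, had −0.27. The labels give no batch, and no biological explanation was tested.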

How the results depend on the processing

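Leaving out mouse 1 of both genotypes, the 2 shallowest oocytes, or genes above 0.3 counts per base, and leaving out each mouse for shares, detection, spread and motif, were chosen after seeing the data. No gene called in the main test changed sign in any alternative. Of 110 named genes besides Zfp36l2, 92 kept their side of the threshold in every alternative that tested them, other than the 1.5-fold minimum, and none reversed; the strict filter tested 102 and the count ceiling 78 of the 111 named genes. Leaving out 1 mouse gave 1359 to 2538 higher and 1219 to 2822 lower genes, 0 to 2 lists higher and 0 to 1 lower (oocyte-specific and maternal-effect genes, without floxed mouse 3). It moved Zfp36l2 between −1 and −0.6 on the log2 scale, never past the threshold; over all alternatives its adjusted p was 0.0859 to 0.587. DESeq2 called 2700 higher and 2724 lower genes, voom on oocytes 3329 and 3414, and the 1.5-fold minimum 847 and 679, by its construction. Without mouse 1 of both genotypes 3182 were higher and 3549 lower. The number of camera lists higher fell from 2 to 1 with voom. It fell to 0 with an estimated correlation (0 also at an unadjusted p), with no or a stricter filter, without the knockout oocytes numbered 8, with thinned oocytes, with limma on mouse means, without mouse 1, without the 2 shallowest oocytes, and among genes under the count ceiling. Apart from the estimated correlation, the cause was not tested; the 2 main lists lay close to the threshold (adjusted p = 0.045).

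The mouse number as a block gave 2876 higher and 2947 lower genes and 0 lists higher (adjusted p = 0.0658 for both main lists). As deviations of log2 CPM of mouse sums from the mean of all 4 mice of a genotype, mice with the same number had r of 0.32, 0, 0.25 and 0.18, and not every mouse correlated best with its own number, so the numbers were not taken as pairing. Without floxed mouse 1, the share differences of theca, stromal and endothelial markers (range over left-out mice −0.0144 to −0.0115 percentage points), blood and immune markers (−0.00405 to −0.00275) and the 10 most abundant genes (−0.154 to −0.0721) passed an adjusted p of 0.05. The difference in genes detected lay between −211.9 and −50.6 over left-out mice, and that in spread between 0.048 and 0.089. The motif odds ratio among higher genes was 0.96 with TTATTTATT in place of TATTTAT and 1.03 to 1.09 over left-out mice; the cause was not tested. The planned limit on shallow oocytes removed none. Zfp36l2 had 389 counts in all floxed oocytes together, and whether depth limited its test was not examined.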

Other observations

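The keratin and myosin heavy chain results, the tests of count flattening and those of Zfp36l2 were chosen after the values were seen; the tests of other splits, of the AU-rich motif and of neighbouring genes were fixed beforehand.

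Among 354 tests of gene families sharing a symbol stem, only keratins and myosin heavy chains passed. Of 28 keratin genes, 13 were lower and none higher in knockout oocytes (Fisher's exact test, adjusted p = 0.00681). Krt73 fell from 29.2 ± 8.38 to 0.874 ± 0.539 CPM (log2 fold change −4.99, SE 0.45), Krt20 from 8.23 ± 1.68 to 0.120 ± 0.22 CPM, and Krt12, a keratin of the cornea, from 90.9 ± 4.26 to 10.0 ± 10.2 CPM. The 13 lie in the keratin clusters of chromosomes 11 and 15. Of 13 myosin heavy chain genes, 8 were lower and none higher (adjusted p = 0.0112). Myh11, of smooth muscle, fell from 268.7 ± 67.0 to 81.8 ± 13.1 CPM and Myh2, of skeletal muscle, from 101.8 ± 11.9 to 42.4 ± 10.8 CPM. The skeletal copies are alike in sequence, so their values are uncertain. Myh1, Myh2, Myh4, Myh8 and Myh13 also lie close together on chromosome 11. Beside these, the share of theca, stromal and endothelial markers was 0.0157% of counts in floxed and 0.00322% in knockout oocytes, without overlap of the mice. Its exact permutation p of 0.0286 (adjusted p = 0.0714) is the smallest that 70 arrangements allow, so that test could hardly pass and decides nothing. Nearly all of the share was Pecam1, which was itself lower (adjusted p = 0.000487). Chromosome 14 had 57 higher and 92 lower genes, the only chromosome whose balance differed (Fisher's exact test, adjusted p = 0.0118). The Fisher tests of families and chromosomes treat genes as independent, whereas neighbouring genes tended to be lower together. Their p-values may therefore be too small.

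Genes lower in knockout oocytes lay next to each other more often than chance. Among 12465 adjacent pairs of non-overlapping genes with different symbol stems, 281 had both members lower, against a mean of 216.9 after shuffling the calls, a ratio of 1.3 (permutation p = 0.0001, the smallest that 10000 shuffles can give). For higher genes the ratio was 1.12 (290 pairs, p = 0.0194). Neighbouring genes may thus share part of their change. Read-through transcripts were not separated from regulation here.

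The higher genes were tested for the loss of a decay signal read by ZFP36L2. The model odds ratio for TATTTAT was 1.084, and its 95% interval of 0.968 to 1.213 includes 1. The outcome set beforehand as speaking against that hypothesis was an interval including 1, but such an interval leaves room for a modest excess, so the question stays open. Genes with 1, 2 and 3 or more sites were higher in 17.1%, 16.1% and 14.7% of cases, and genes with none in 13.9%.

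Chance assignment of mice to groups is argued against for the number of called genes, but not excluded. The real split gave 4148, and of the 35 splits of the 8 mice only 1, the real one, gave as many. The highest other split gave 0 by edgeR, with up to 2635 genes at an unadjusted p under 0.05. Every other split mixes the genotypes, which widens the spread within its groups and makes calls unlikely. A share of 1 in 35 is also the smallest that this test can give.

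Zfp36l2 counts in oocytes labelled knockout were at 61.1% of the floxed level, a difference that did not pass the test (adjusted p = 0.208) and whose 95% interval runs from slightly higher to 3.38-fold lower. Single mislabelled oocytes are argued against: all 50 oocytes fell on the side of their label in genes called without their own mouse. A swap of the group names as a whole would give the same result, so this check cannot tell which group carries the deletion. Too few reads to see a complete loss are argued against by the 226 counts in knockout oocytes. Reads from exons outside the deletion could account for the remaining counts, and this cannot be told apart from transcripts left by incomplete deletion, since counts per exon are not used here.

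Counts of abundant genes flattened: Usp9x held the highest count, 8354, while Zp3 never exceeded 2257 and Gdf9 3195. The slope of count on depth fell with counts per base at a given mean count (partial rho −0.43 over 9218 genes), which is consistent with counting read pairs with the same ends once. A fixed limit of reads per position cannot be told apart from that: 4 genes exceeded 2 counts per base in any oocyte and 1.17% exceeded 1. The median size of called log2 fold changes fell from 1.77 in genes under 0.05 counts per base to 0.33 at 0.8 or more. That fall may in part reflect the smaller changes that can be called in abundant genes. Over all tested genes, called or not, the median size fell from 0.79 to 0.16 between the same classes. No biological explanation was tested.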
